A study of Caenorhabditis elegans with 6 samples.

How the data were processed

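Messenger RNA was measured by sequencing in 6 samples of whole L4 hermaphrodites heterozygous for rpl-36A(P55Q) over the balancer mIn1, 3 grown without CHX for 2 days and 3 with CHX for 3 days. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, RNA was extracted with Trizol, ribosomal RNA was depleted with RNase H, and libraries were made with a SMARTER kit. The authors deposited raw read counts over the coding region of 1 transcript for each of 20189 protein-coding genes, with WBcel235 coordinates in the row names per the file headers. The submitters' processing notes name WBcel235 and DESeq2, without a version. The aligner, the counting program, the use of strand, and the treatment of duplicates and of reads that match several places are not given in the sources used here. Reads shared between near-identical copies, between overlapping genes or with an antisense partner therefore cannot be told apart, which bears on sperm protein, yolk protein, histone, collagen and small heat shock protein genes. The kit amplifies complementary DNA, and without molecular identifiers reads are not independent molecules, so counting intervals cover counting error only. Counts over coding sequence leave out untranslated regions.

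Depth was low, between 313767 and 414781 counts per sample, and 3 counts, the floor used here, correspond to between 7.23 and 9.56 CPM of a library's raw total. Between 10368 and 10969 genes had a count in a sample. Differences between replicates of a group exceeded sampling noise for every pair (chi-square over degrees of freedom 2.24 to 3.49 within groups and 6.08 to 9.02 between groups), so no pair looked like the same library deposited again. Separate libraries from the same RNA would also exceed sampling noise, so this does not show that the replicates are biological. The common biological coefficient of variation was 19.0%. No sequencing batch or date is given in the labels. Drug and age change together, so age could not be a term of the model.

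Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 5641 genes with 94.1% of counts. TMM factors, robust quasi-likelihood fits and the quasi-likelihood F-test of treatment were used, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors of log2 fold changes were computed as the absolute log2 fold change divided by the square root of F. Fold values are those of the fitted model, CPM are counts scaled by the library's counts in tested genes times its TMM factor, and n is 3 per group throughout. For genes with 3 or fewer counts in a group, and for genes among the largest changes with 4 to 9, the ratio of summed counts, scaled to the libraries' effective sizes, with its exact 95% counting interval is given instead. Gene lists (45, of which 43 had 3 or more tested members) and classes of genes with a shared symbol prefix (45 with 10 or more tested members) were tested with camera from limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and lists also with fry. Camera with an estimated correlation also uses only the few degrees of freedom left by the samples. A call can therefore be lost there without correlation between genes. Shares of counts were compared by exact two-sided permutation tests, whose smallest p with 3 against 3 is 0.1. Gene symbols came from the table and from a name table that matched 19878 of the identifiers. Exon numbers and coding lengths came from the Ensembl annotation of the same build, in which 18408 of the transcripts were found. Figures were drawn with matplotlib 3.10.9.

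The test was checked on simulated counts for the 5641 genes, drawn with the means and library sizes of these samples. It recovered 5 of 67 genes changed 1.5-fold, 33 of 67 changed 2-fold and 61 of 66 changed 4-fold, with 2 false calls. A planted list shifted by 0.8 was called with the preset and with the estimated correlation (adjusted p 1.87e-16 and 0.0258), and 0 of 40 unchanged lists were called with either. Genes were drawn independently of each other in this simulation. In the real lists the estimated correlation ran from -0.168 (translation surveillance) to 0.929 (yolk proteins). The simulation therefore cannot show how often the preset correlation gives false calls for lists whose genes move together.

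The lists, the test, the alternatives and the rule for naming genes were fixed before the data were examined. The rule took the 10 genes higher and the 10 lower with the largest change among called genes with a mean of at least 5 CPM and no overlap between groups. It also took the mutated gene, for each list up to 4 members (the 2 called with the smallest p and the 2 most abundant), all members of the translation surveillance, yolk protein and nonsense-mediated decay lists, and for each class the member with the smallest p. Genes named outside the rule are glh-1, tdo-2, his-70, his-71 and nduo-4 and the genes of neighbour runs, which were chosen after their values were seen. Alternatives were RLE, upper-quartile and library-total scaling, DESeq2 1.42.0, limma-voom, no filter beyond 1 count and a filter at 5 CPM in 3 samples, each replicate left out in turn, the replicate number as a block, and sperm, collagen and yolk genes left out. List results with library totals and upper-quartile factors, counts of list members without each replicate, and estimated correlations without each replicate, with library totals and with the 5 CPM filter, were added after seeing the data. The filter at 5 CPM was looser than the main one, with 9701 genes tested, and lies below the floor of 3 counts. No genome sequence was used here, so GC content was not tested.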

Results

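The data are messenger RNA counts from whole Caenorhabditis elegans hermaphrodites at the L4 stage, the last larval stage before adulthood. Every animal was heterozygous for rpl-36A(P55Q), an altered allele of a gene for a protein of the large ribosomal subunit, over mIn1, a balancer of chromosome II that carries the unaltered copy. Synchronized eggs had been placed on growth plates without cycloheximide (CHX), a drug that blocks translation elongation at the ribosome's E site, or on plates with 500 µg/ml of it, and were kept at 23 °C. Animals without CHX were collected after 2 days and animals on CHX after 3 days, so the groups, which the design text calls matched at L4, differ in age as well as in drug. There were 3 samples per group. The series title names ribosomes resistant to CHX, and the question of the comparison is which transcripts differ when such heterozygotes reach L4 on the drug. The libraries were shallow. Total counts in coding sequences were 352510, 360924 and 313767 in the samples without CHX and 385500, 391235 and 414781 in those with CHX. The means were 342400 ± 25152 and 397172 ± 15517 (SD, n = 3), and the exact two-sided permutation p was 0.1, the smallest that 3 samples against 3 allow. Of 20189 protein-coding genes, 13894 had a count in any sample and 5641 had enough counts to be tested. The labels do not say whether the replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

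Animals grown on CHX had higher levels of 26 of 27 tested oocyte genes, 14 of 26 cell cycle genes and 13 of 38 germline genes than animals grown without it. They had lower levels of 54 of 94 collagen, 17 of 20 body wall muscle, 13 of 22 sperm, 18 of 60 oxidative phosphorylation and 24 of 78 ribosomal protein genes. The lists were called with a preset correlation between genes, and none was with an estimated one (smallest adjusted p 0.124). The latter test also has fewer degrees of freedom, so correlation alone need not account for the lost calls. The fall of ribosomal protein genes (median log2 fold change -0.27) was not larger than that of other genes matched on abundance and coding length, whose list medians centred on -0.38. The pool for matching included the other lists that fell. With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 1419 of the 5641 tested genes differed, 579 of them higher and 840 lower on CHX. DESeq2 called 907 genes, 348 higher and 559 lower, and without CHX replicate 3 the quasi-likelihood test called 383 higher. At least a 2-fold change was seen for 907 genes, 391 higher and 516 lower. The first principal component held 53.8% of the variance and separated the groups. The split between higher and lower depends on the scaling. With library totals alone in place of TMM factors, 851 genes were higher and 605 lower, and the median log2 fold change of tested genes moved from 0.02 to 0.18. In a simulation with these depths and this spread, the test recovered 7.46% of genes changed 1.5-fold, 49.3% of those changed 2-fold and 92.4% of those changed 4-fold. The simulation changed 67, 67 and 66 genes at these folds, far fewer than the 1419 called here. Its adjusted threshold was therefore stricter, and the shares may understate recovery in these data. A gene without a call is still not shown to be unchanged.

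Among called genes with a mean of at least 5 CPM and no overlap between groups, the largest fitted rise was in F55G11.4 (WBGene00010124). Counting intervals of thinly counted genes below reach larger ratios. F55G11.4 encodes a CUB-like domain protein and lies on chromosome IV from 12973624 to 12975591 in WBcel235 coordinates, with 8 exons. Levels are given as CPM, counts scaled to the size of each library. That of F55G11.4 went from 23.6 ± 11.4 to 597 ± 88.6 CPM (SD, n = 3), a 24.5-fold rise (log2 fold change 4.62, SE 0.28, adjusted p 3.03e-13). A related gene on the same chromosome, dod-24 (12940106 to 12941405), named as a target downstream of the insulin pathway factor DAF-16, rose from 5 counts over the samples without CHX to 109 with it, a ratio of 16.8 (95% counting interval 7.0 to 52.9; adjusted p 3.03e-06). C50F7.5 rose from 38.1 ± 18.3 to 399 ± 72.3 CPM, and C14C6.5 from 46.3 ± 8.51 to 459 ± 53.0 CPM. On chromosome X, Y62H9A.5 (11882144 to 11882917) and its neighbour Y62H9A.3 (11879110 to 11879971) both rose. Y62H9A.5 had 5 counts without CHX and 105 with it (interval 6.73 to 51.0), and Y62H9A.3 had 2 and 44 (ratio 17, interval 4.43 to 145). The acyltransferase gene dgtr-1 had 2 and 47 counts (ratio 18.1, interval 4.75 to 154), and F14D7.2 had 3 and 57 (ratio 14.7, interval 4.77 to 73.2). The 10 largest rises were completed by gpd-1, for the glycolytic enzyme glyceraldehyde-3-phosphate dehydrogenase, with 4 and 53 counts (ratio 10.2, interval 3.77 to 38.9) and a close paralog with which it may share reads, and by R04D3.2, with 4 and 52 (interval 3.69 to 38.2). All 4 counts of R04D3.2 without CHX lay in no_CHX replicate 1. Counting intervals cover counting error only.

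Within the same limits, the largest fall was in F27E5.3 (WBGene00009193, chromosome II, 10141457 to 10144192). It had 53 counts over the 3 samples without CHX and 1 count with CHX, a ratio of 0.0146 (95% counting interval 0.000362 to 0.0847). C15H7.4 had 31 and 3 counts (ratio 0.0747, interval 0.0146 to 0.24). Better measured was ant-1.4 (WBGene00020140; chromosome IV, 8459178 to 8460327, 3 exons), a mitochondrial ADP/ATP carrier gene, which fell from 166 ± 24.5 to 20.2 ± 1.74 CPM, 8.06-fold (log2 fold change -3.01, SE 0.35, adjusted p 2.26e-07). The gene pud-4 (chromosome V, 2326678 to 2327262) fell from 107 ± 14.2 to 13.5 ± 5.22 CPM, and grl-27, of the ground-like family related to hedgehog, fell from 57 counts to 6 (ratio 0.0813, interval 0.0286 to 0.188). B0207.7 had 46 and 5 counts (ratio 0.0839, interval 0.026 to 0.21), B0393.4 54 and 7 (interval 0.0384 to 0.221) and R102.4 69 and 9 (interval 0.0442 to 0.202). The other 2 were ZC581.2 with 43 and 6 counts (interval 0.0375 to 0.254) and F09C12.8 with 46 and 7 (interval 0.0448 to 0.262). Among these 20 genes the largest adjusted p was 0.00283, and each was called under all 15 alternative settings.

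The mutated gene itself had no detectable difference at this depth. Its entry, rpl-36.A (WBGene00004454; chromosome II, 11096542 to 11097204, minus strand, 3 exons), stood at 219 ± 40.8 CPM without CHX and 195 ± 40 with it (SD, n = 3; log2 fold change -0.17, SE 0.23, adjusted p 0.613), and counts per gene cannot tell the alleles apart. Of 78 tested genes for cytosolic ribosomal proteins, 24 fell and 0 rose (26 and 0 adjusted over the list alone), with a median log2 fold change of -0.27. The list was called by camera with a preset correlation (adjusted p 8.96e-05), and the adjusted p was 0.169 with an estimated correlation. Transcripts of rpl-4 fell from 4963 ± 561 to 3268 ± 106 CPM and those of rps-0 from 3704 ± 564 to 2462 ± 79.2 CPM. Random lists of other genes matched on abundance and coding length, from a pool that included collagens and other lists that fell, had a median of -0.38. With library totals alone the median was -0.11 and 10 ribosomal protein genes were lower, and 13 were without CHX replicate 2 or without CHX replicate 3.

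Other parts of the translation machinery showed few calls. Of 47 ribosome biogenesis genes 6 were lower (5 adjusted over the list alone; camera adjusted p 0.19), among them fib-1, for fibrillarin, at 1187 ± 224 and 757 ± 43.1 CPM, and K07H8.10, which fell 1.65-fold. Of 40 translation factors 4 were lower (0 adjusted over the list alone; camera adjusted p 0.227), and with library totals alone 0 were lower and 1 was higher. The number lower was 0 without CHX replicate 2, 1 without CHX replicate 3 and 2 without any of the no_CHX replicates. Of 21 aminoacyl-tRNA synthetases 1 was lower, fars-3 (0 adjusted over the list alone; camera adjusted p 0.936), a call lost in 11 of 15 alternatives, among them DESeq2, library totals, both other filters and each replicate left out other than no_CHX replicate 2 (adjusted p 0.0306 to 0.19 over the alternatives). Of 51 mitochondrial ribosomal protein genes 5 were lower (0 adjusted over the list alone, camera adjusted p 0.201). That count was 0 without CHX replicate 3, 1 without CHX replicate 2 or no_CHX replicate 1, and 3 without CHX replicate 1 or no_CHX replicate 3. With library totals 2 were lower, and with DESeq2 0 passed. None of 33 proteasome subunit genes passed edgeR's test, DESeq2 or limma-voom (0 adjusted over the list alone; 1, 0 and 1 at an unadjusted p under 0.05; camera adjusted p 0.803).

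Genes of the response to blocked translation were mostly without a call. Of 5 tested translation surveillance genes, 1 rose (1 adjusted over the list alone; camera adjusted p 0.936). This was pgp-5, a P-glycoprotein transporter gene, at 25.5 ± 16.3 and 69.3 ± 14.6 CPM (log2 fold change 1.40, SE 0.46, adjusted p 0.0247). Its adjusted p was 0.0531 without no_CHX replicate 1, 0.107 without no_CHX replicate 3, 0.0998 without CHX replicate 1, 0.0671 without CHX replicate 3 and 0.0899 with DESeq2, and its log2 fold change was 2.00 without no_CHX replicate 2. The transcription factor gene zip-2 (log2 fold change 0.10, SE 0.18), cebp-1 (-0.39, SE 0.32), the kinase gene kgb-1 (-0.88, SE 0.43) and pgp-6 (-0.08, SE 0.43) did not pass. Among 8 nonsense-mediated decay factors smg-3 alone passed edgeR's test with all samples (log2 fold change 0.85, SE 0.30, adjusted p 0.039; 0 adjusted over the list alone), and its adjusted p was 0.176 without no_CHX replicate 1, 0.113 without CHX replicate 2, 0.111 without CHX replicate 3 and 0.111 with DESeq2. The others lay between 0.00 for smg-2 and 0.70 for smg-4, with smg-1, smg-6, smg-8, smgl-1 and smgl-2 in that range, and smg-4 passed without no_CHX replicate 2 (log2 fold change 1.51, adjusted p 0.0281). Camera did not call the list (median 0.37, adjusted p 0.26), and its median was 0.18 without no_CHX replicate 2 or CHX replicate 2. With the looser filter at 5 CPM camera called it (adjusted p 0.0485, and adjusted p 0.237 with an estimated correlation). Of 8 integrated stress response genes 1 fell (1 adjusted over the list alone; camera adjusted p 0.216), cth-2, for a cystathionine gamma-lyase, from 808 ± 74.3 to 321 ± 29 CPM.

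Oocyte and eggshell genes rose almost without exception. Of 27 tested, 26 were higher and 1 was lower (the same counts adjusted over the list alone), and their median log2 fold change was 1.43. Together they took 0.574% ± 0.0864 of counts without CHX and 1.75% ± 0.062 with it (SD, n = 3; exact permutation p 0.1, the smallest possible). The eggshell gene cpg-1 (chromosome III, 4489359 to 4491392, 4 exons) went from 795 ± 78.8 to 2749 ± 114 CPM, 3.46-fold (log2 fold change 1.79, SE 0.12, adjusted p 8.41e-12), and cpg-2 and cbd-1, also of the eggshell, rose 2.70-fold and 2.42-fold. The member that fell was tdo-2, a tryptophan dioxygenase gene, named after its value was seen; 0 were lower with library totals or without no_CHX replicate 1, no_CHX replicate 2, CHX replicate 2 or CHX replicate 3. The list was called by camera (adjusted p 1.69e-32), and the adjusted p was 0.124 with an estimated correlation.

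Germline genes outside that list had a smaller median. Of 38, 13 rose and 1, glh-1, fell (the same counts adjusted over the list alone; median 0.48, camera adjusted p 7.68e-04, and adjusted p 0.124 with an estimated correlation). The RNA-binding protein gene mex-3 rose 2.71-fold, gld-3 2.47-fold and cey-2 1.38-fold, while cgh-1 was at 1387 ± 242 and 1720 ± 103 CPM without a call (adjusted p 0.0781), although it passed without no_CHX replicate 1 (0.00606), with library totals (0.00546), upper-quartile factors (0.0482) and limma-voom (0.0464). The cey-2 call was lost without no_CHX replicate 2 (adjusted p 0.0868), no_CHX replicate 3 (0.0587) or CHX replicate 2 (0.0739). Cell cycle genes rose in 14 of 26 cases with 0 lower (19 and 0 adjusted over the list alone; median 0.83, camera adjusted p 7.02e-09, and adjusted p 0.124 with an estimated correlation). Among them the ribonucleotide reductase gene rnr-2 rose 2.55-fold and the cyclin B gene cyb-3 2.48-fold. Of 20 histone genes 10 were higher and 2 lower (11 and 2 adjusted over the list alone; median 0.73, camera adjusted p 0.00267, and adjusted p 0.241 with an estimated correlation). The variant gene htz-1 rose 3.10-fold and his-67 2.71-fold, and the H3.3-type genes his-70 and his-71, named after their values were seen, fell. The number of histone genes lower was 0 without no_CHX replicate 1, no_CHX replicate 2 or CHX replicate 3, and 1 without no_CHX replicate 3 or CHX replicate 1 and with library totals. Reads of near-identical histone copies may be shared. Counts of higher germline and histone genes were 6 and 5 without CHX replicate 3, and 8 germline genes were higher without CHX replicate 2.

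Of 22 tested sperm genes, 13 were lower and 0 higher (16 and 0 adjusted over the list alone), with a median of -0.97, and their share of counts went from 0.225% ± 5.56e-04 to 0.134% ± 0.0177 (SD, n = 3; exact permutation p 0.1). The sperm phosphatase gene gsp-3 fell from 181 ± 5.09 to 72.1 ± 21.2 CPM and ssq-2 from 393 ± 64.4 to 206 ± 32.8 CPM. The list was called by camera (adjusted p 2.13e-04; adjusted p 0.147 with an estimated correlation), and major sperm protein genes are near-identical copies that may share reads. The number lower was 7 with library totals or without CHX replicate 3, and 8 without no_CHX replicate 1, no_CHX replicate 2 or CHX replicate 2. With DESeq2, 4 sperm genes passed the threshold in either direction. Yolk protein transcripts showed no difference that passed edgeR's test with all samples and the default filter (0 of 6, also adjusted over the list alone; 1 at an unadjusted p under 0.05; camera adjusted p 0.201), and DESeq2 called 0 too. Limma-voom called vit-3 lower (adjusted p 4.70e-05), as did edgeR's test without a low-count filter (2.95e-06), with a replicate block (0.0151) and without CHX replicate 1 (0.0125) or CHX replicate 3 (0.0283). With a replicate block vit-6 passed as well (0.0391). The values of vit-6 were 7444 ± 296 and 5516 ± 2591 CPM and those of vit-2 5855 ± 781 and 5201 ± 1707 CPM. For vit-1, vit-3, vit-4 and vit-5 the log2 fold changes were -1.26, -1.96, -0.70 and -0.65, and several of these genes are close copies. In CHX replicate 2 yolk transcripts were a median of 1.76 (log2) above the other CHX samples. Without it all 6 yolk genes were lower, those 4 with log2 fold changes of -2.15, -3.43, -2.44 and -1.44. The list was then called lower by camera (median -1.79, adjusted p 3.08e-11), and the adjusted p was 0.175 with an estimated correlation. The median was -0.38 without CHX replicate 1 and -0.30 without CHX replicate 3, and camera did not call the list in either case (adjusted p 0.225 and 0.216).

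**Figure D1:**
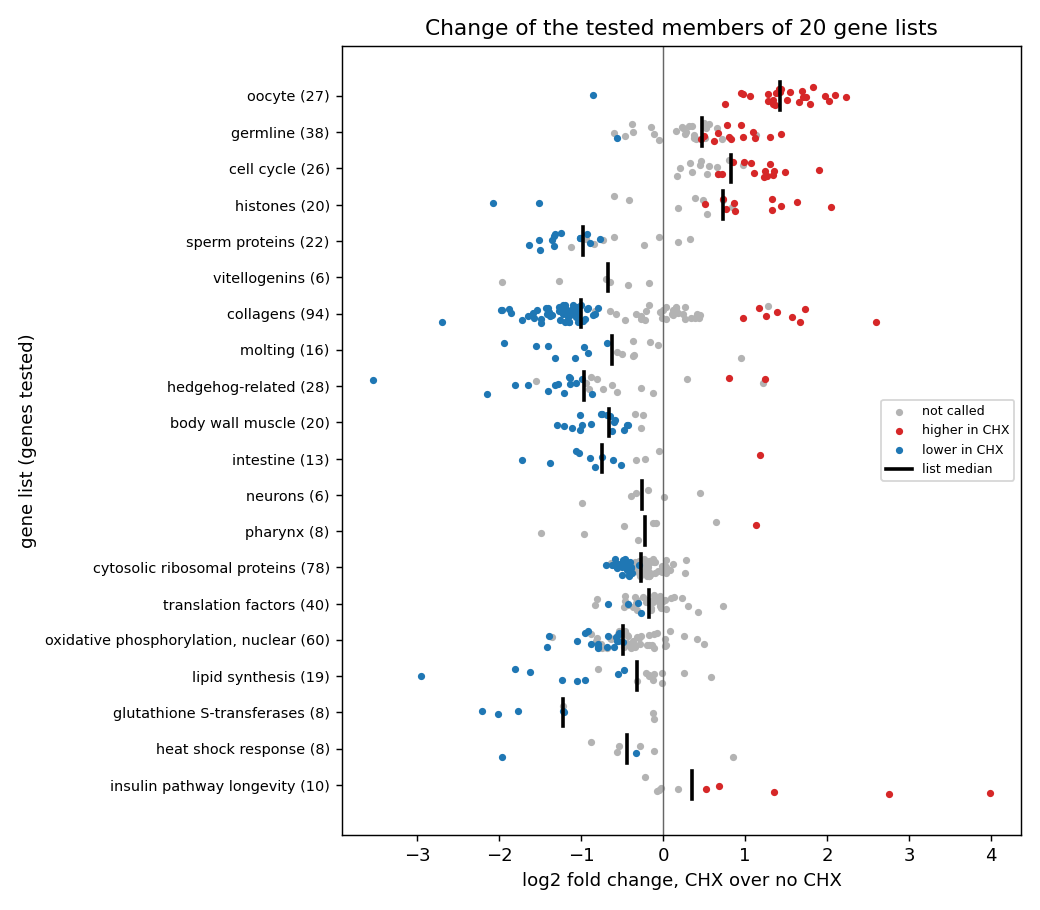
Log2 fold change on CHX over no CHX for each tested gene of 20 gene lists, 1 point per gene; red and blue points are genes called higher and lower, grey points were not called, and black bars are list medians. Oocyte genes lie to the right with a median of 1.43 and collagens mostly to the left with a median of -1.01.

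Of 94 tested collagen genes 54 fell and 8 rose (55 and 9 adjusted over the list alone; median -1.01, camera adjusted p 6.08e-13, and adjusted p 0.15 with an estimated correlation), and their share of counts went from 5.09% ± 0.26 to 3.55% ± 0.0804 (SD, n = 3; exact permutation p 0.1). The gene col-175 (chromosome X, 9233638 to 9234618) fell from 2524 ± 249 to 964 ± 150 CPM and col-73 from 2535 ± 21.9 to 1105 ± 136 CPM. Adult cuticle collagens, all 6 of which are also in the collagen list, went both ways (1 higher and 1 lower, the same adjusted over the list alone; camera adjusted p 0.939). Among them col-119 rose 2.39-fold, col-63 fell 2.67-fold and col-129 was at 1366 ± 170 and 1545 ± 233 CPM without a call. Molting genes fell in 8 of 16 cases with 0 higher (the same adjusted over the list alone; median -0.63, camera adjusted p 0.00238, and adjusted p 0.324 with an estimated correlation). These included ptr-18, which fell 2.64-fold, mlt-8, which fell 2.93-fold, and lin-42, the period homolog that cycles with the molts, at 490 ± 165 and 251 ± 90.5 CPM. Without no_CHX replicate 2 or CHX replicate 3, 5 molting genes were lower, and the median was -1.0 without CHX replicate 1.

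Hedgehog-related genes, many of which act in the epidermis, fell in 14 of 28 cases and rose in 2, or in 1 without no_CHX replicate 2 (16 and 3 adjusted over the list alone; median -0.96, camera adjusted p 1.63e-05, and adjusted p 0.195 with an estimated correlation). The ground-like gene grl-16 fell from 2187 ± 283 to 995 ± 111 CPM and wrt-4 from 238 ± 17.4 to 53.5 ± 33.9 CPM (log2 fold change -2.15, and -2.75 without CHX replicate 1), whereas ptc-1, a patched homolog that acts in the germline, rose 2.36-fold. Of 7 heterochronic genes, which time larval development, 1 rose and 1 fell (1 and 2 adjusted over the list alone; camera adjusted p 0.936), and they were lin-41, which rose from 120 ± 4.02 to 368 ± 48.1 CPM, and lin-42. Without no_CHX replicate 3, 2 were lower. Of 5 genes of the hypodermis and seam 1 rose (0 without CHX replicate 3) and 2 fell (the same adjusted over the list alone; camera adjusted p 0.273), the last being let-805, which fell 2.1-fold, and vab-10, which fell 1.74-fold, which encode parts of the epidermal attachment to muscle. Over the heterochronic list the median was positive and the mean negative, and over the translation surveillance list the reverse held; camera pointed up for both lists. The heterochronic median was negative without no_CHX replicate 2, no_CHX replicate 3 or CHX replicate 1, and the surveillance median was positive without no_CHX replicate 1 or CHX replicate 1, with library totals and with a filter at 5 CPM.

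Body wall muscle transcripts were lower on CHX in 17 of 20 cases with 0 higher (the same adjusted over the list alone; median -0.66). The basement membrane perlecan gene unc-52 (chromosome II, 14647325 to 14666943, 35 exons) fell from 1928 ± 249 to 788 ± 111 CPM (log2 fold change -1.29, SE 0.14, adjusted p 5.15e-08), and the myosin heavy chain genes myo-3 and unc-54 fell 2.32-fold and 1.68-fold. Their share of counts went from 1.47% ± 0.227 to 0.978% ± 0.0258 (SD, n = 3; exact permutation p 0.1). Camera called the list (adjusted p 6.64e-08), and the adjusted p was 0.31 with an estimated correlation. The number lower was 10 with library totals or without CHX replicate 3, and 11 without no_CHX replicate 2. Intestinal genes fell in 9 of 13 cases and rose in 1 (the same adjusted over the list alone; median -0.74, camera adjusted p 0.00248, and adjusted p 0.15 with an estimated correlation). The protease gene cpr-6 fell from 2283 ± 330 to 1122 ± 199 CPM and asp-1 from 3386 ± 438 to 2375 ± 47.5 CPM, while cpr-1, another cathepsin B-like protease gene, rose from 302 ± 42.4 to 685 ± 17.2 CPM.

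Other tissues gave few measurable markers. Of 8 pharynx genes 1 was higher, tnt-4 (0 adjusted over the list alone; camera adjusted p 0.785), a call lost in 6 of 15 alternatives, namely without no_CHX replicate 1 (adjusted p 0.139), no_CHX replicate 3 (0.168), CHX replicate 1 (0.0936) or CHX replicate 3 (0.185), with DESeq2 (0.141) and with a replicate block (0.0531), while the pharyngeal myosin gene myo-2 was at 146 ± 26.8 and 118 ± 15.7 CPM. None of 6 neuronal genes passed edgeR's test (0 adjusted over the list alone and 0 at an unadjusted p under 0.05; 0 with DESeq2 or limma-voom; camera adjusted p 0.803), with egl-3 at 128 ± 28.5 and 97.9 ± 1.12 CPM. Of 5 neuropeptide genes 2 were lower (the same adjusted over the list alone; camera adjusted p 0.469), nlp-77, at 973 ± 163 and 635 ± 71.3 CPM, and the thinly counted nlp-36, whose call was lost in 12 of 15 alternatives, among them each replicate left out, library totals, DESeq2, limma-voom and both other filters (adjusted p 0.0405 to 0.154 over the alternatives). None of 4 coelomocyte, excretory and gland genes passed edgeR's test (0 adjusted over the list alone and 0 at an unadjusted p under 0.05; 0 with DESeq2 or limma-voom; camera adjusted p 0.939), among them vha-8, at 190 ± 34.8 and 135 ± 14.1 CPM.

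Of 60 oxidative phosphorylation genes 18 fell and 0 rose (21 and 0 adjusted over the list alone; median -0.48, camera adjusted p 1.63e-05, and adjusted p 0.124 with an estimated correlation). This list, meant for nuclear genes, also took in 3 genes of the mitochondrial genome, of which nduo-2 and nduo-4 were among those that fell. The nduo-2 call was lost with library totals and DESeq2 and without no_CHX replicate 2, CHX replicate 1 or CHX replicate 3 (adjusted p up to 0.106). The ATP synthase gene atp-2 fell from 5445 ± 450 to 3378 ± 99.6 CPM and gas-1, for a complex I subunit, from 389 ± 54.6 to 145 ± 15.5 CPM. The number lower was 10 with library totals or without CHX replicate 1. Of 9 mitochondrially encoded genes 4 fell (5 adjusted over the list alone; camera adjusted p 0.0539, and adjusted p 0.527 with an estimated correlation), among them ctb-1, for cytochrome b, at 890 ± 66.9 and 592 ± 45 CPM. That list was called without no_CHX replicate 1 (camera adjusted p 0.00114), CHX replicate 1 (0.0396) or CHX replicate 2 (0.0364) and with the looser filter at 5 CPM (0.0191). In the same order the adjusted p was 0.316, 0.584, 0.559 and 0.489 with an estimated correlation. Of these genes 7 were lower without no_CHX replicate 1, 2 without no_CHX replicate 3, CHX replicate 1 or CHX replicate 2, and 1 without no_CHX replicate 2 or CHX replicate 3 and with library totals.

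Of 19 lipid synthesis genes 8 fell and 0 rose (the same adjusted over the list alone; median -0.32, camera adjusted p 0.0106, and adjusted p 0.318 with an estimated correlation). They included the desaturase gene fat-6, which fell 1.93-fold, and the elongase gene elo-6, which fell 2.07-fold, while pod-2, for acetyl-CoA carboxylase, was at 1201 ± 54.3 and 1191 ± 159 CPM. The number lower was 5 with library totals or without CHX replicate 2, and the median was -0.17 with library totals, -0.55 without no_CHX replicate 3 and -0.49 without CHX replicate 2. Fasting and beta-oxidation genes fell in 4 of 22 cases (the same adjusted over the list alone; median -0.23, camera adjusted p 0.0267, and adjusted p 0.291 with an estimated correlation). The acyl-CoA dehydrogenase gene acdh-1 (chromosome I, 6497436 to 6499560, 7 exons) fell from 989 ± 69.8 to 319 ± 38.6 CPM (log2 fold change -1.63, SE 0.16, adjusted p 1.09e-08) and ech-6, for an enoyl-CoA hydratase, from 550 ± 81.5 to 179 ± 24.1 CPM. The call of this list was lost without no_CHX replicate 3 (camera adjusted p 0.081) or CHX replicate 1 (0.0973), and its median was -0.07 with library totals, -0.38 without no_CHX replicate 2 and -0.13 without no_CHX replicate 3.

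Genes of families that include detoxification enzymes differed in both directions. Membership of a family does not show that a gene acts in detoxification. Glutathione S-transferase genes fell in 5 of 8 cases with 0 higher (6 and 0 adjusted over the list alone; median -1.22, camera adjusted p 0.0037, and adjusted p 0.153 with an estimated correlation), among them gst-36, which fell 2.34-fold, and gst-13, which fell 4.62-fold. UDP-glucuronosyltransferase genes fell in 8 of 17 cases and rose in 3 (the same adjusted over the list alone; median -0.93, camera adjusted p 0.0342, and adjusted p 0.341 with an estimated correlation), with ugt-22 falling 6.38-fold and ugt-29 rising 4.18-fold. Without no_CHX replicate 2 the glucuronosyltransferase call was lost (camera adjusted p 0.108) and 3 transferases of the glutathione family were lower. Without CHX replicate 3 the numbers lower were 3 and 5 for these families in the same order, and without no_CHX replicate 1 the glutathione median was -1.85. Cytochrome P450 genes rose in 4 of 9 cases with 0 lower (the same adjusted over the list alone; camera adjusted p 0.0811), with cyp-14A5 at 9.79 ± 3.07 and 66.4 ± 20.7 CPM and cyp-31A2 at 37.7 ± 19.1 and 127 ± 15.7 CPM. On chromosome IV, cyp-31A2 lies in a run of neighbouring higher genes with the eggshell gene cbd-1, so its rise need not belong to a response to the drug. The number of P450 genes higher was 2 without no_CHX replicate 2 or no_CHX replicate 3, and 1 was lower without no_CHX replicate 1, no_CHX replicate 3, CHX replicate 2 or CHX replicate 3. The P450 median, 0.97, was -0.09 without CHX replicate 1, 0.06 without CHX replicate 3 and -0.32 with a filter at 5 CPM. Of 32 ABC transporter genes 4 rose and 8 fell (the same adjusted over the list alone; camera adjusted p 0.186), with mrp-4 rising 2.33-fold and pmp-5 falling 3.23-fold. The number that rose was 1 without CHX replicate 3 and 2 without no_CHX replicate 1, no_CHX replicate 3 or CHX replicate 2.

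Camera with all samples did not call the 4 stress response lists that follow. Of 8 heat shock genes 2 fell (3 lower and 1 higher adjusted over the list alone; camera adjusted p 0.201), one of them hsp-16.2, at 70 ± 1.01 and 17.6 ± 4.38 CPM, which has close copies, while hsp-90 was at 3541 ± 546 and 3279 ± 213 CPM. Of 19 genes of the endoplasmic reticulum unfolded protein response 1 rose and 5 fell (the same adjusted over the list alone; camera adjusted p 0.201), with sec-61 at 1993 ± 225 and 1041 ± 66.6 CPM. Without no_CHX replicate 1 both lists were called lower by camera (adjusted p 0.0299 and 0.0351, and adjusted p 0.487 and 0.464 with an estimated correlation). The number of heat shock genes lower was 4 without that replicate and 1 without no_CHX replicate 3, CHX replicate 2 or CHX replicate 3 and with library totals. Of the reticulum list, 0 were higher without no_CHX replicate 2, no_CHX replicate 3, CHX replicate 1 or CHX replicate 2, and 2 were with library totals. Of 11 genes of the mitochondrial unfolded protein response 2 fell (the same adjusted over the list alone; camera adjusted p 0.262), with the chaperonin gene hsp-60 at 2831 ± 209 and 1674 ± 57.6 CPM. For that list 1 was lower with library totals or without no_CHX replicate 3 or any of the CHX replicates. Of 15 oxidative stress genes 3 fell (the same adjusted over the list alone; camera adjusted p 0.349), 4 of the 15 being glutathione S-transferase genes already counted. The test of movement in one direction, fry, which does not compare a list with other genes, called the mitochondrial response lower (adjusted p 0.004) and oxidative stress lower (0.00962), and not heat shock (0.146) or the reticulum list (0.15).

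Genes tied to the insulin pathway and longevity rose in 5 of 10 cases with 0 lower (the same adjusted over the list alone; median 0.35, camera adjusted p 9.27e-04, and adjusted p 0.161 with an estimated correlation). The lysozyme gene lys-7 (chromosome V, 3481421 to 3482600, 3 exons) rose from 66.0 ± 13.4 to 444 ± 88.7 CPM (log2 fold change 2.75, SE 0.24, adjusted p 1.48e-09), and sip-1, for a small heat shock protein of embryos, from 983 ± 308 to 2504 ± 205 CPM. The number higher was 3 without no_CHX replicate 2, no_CHX replicate 3, CHX replicate 1 or CHX replicate 2, and the median was 0.22 without no_CHX replicate 2, 0.14 without no_CHX replicate 3 or CHX replicate 3, and -0.02 without CHX replicate 1. Among immune genes, lysozymes and saposins fell in 7 of 15 cases and rose in 1 (8 and 1 adjusted over the list alone; median -0.65, camera adjusted p 0.0886), with spp-17 falling 3.62-fold and ilys-5 2.45-fold. Their number lower was 4 with library totals or without no_CHX replicate 3 or CHX replicate 1. C-type lectin genes went both ways (4 higher and 5 lower of 25, the same adjusted over the list alone; camera adjusted p 0.986), with clec-87 rising 4.55-fold and clec-41 2.93-fold. Of 6 F-box genes 1 rose (the same adjusted over the list alone; camera adjusted p 0.144), fbxa-215, at 46.0 ± 31.1 and 142 ± 31.8 CPM (log2 fold change 1.64, and 2.29 without no_CHX replicate 3), and 2 rose with library totals or without no_CHX replicate 2. Too few genes of the intracellular pathogen response (1 of 48, skr-3) and of the epidermal antimicrobial peptides (1 of 22, nlp-24) had counts for a test of the list.

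**Figure D2:**
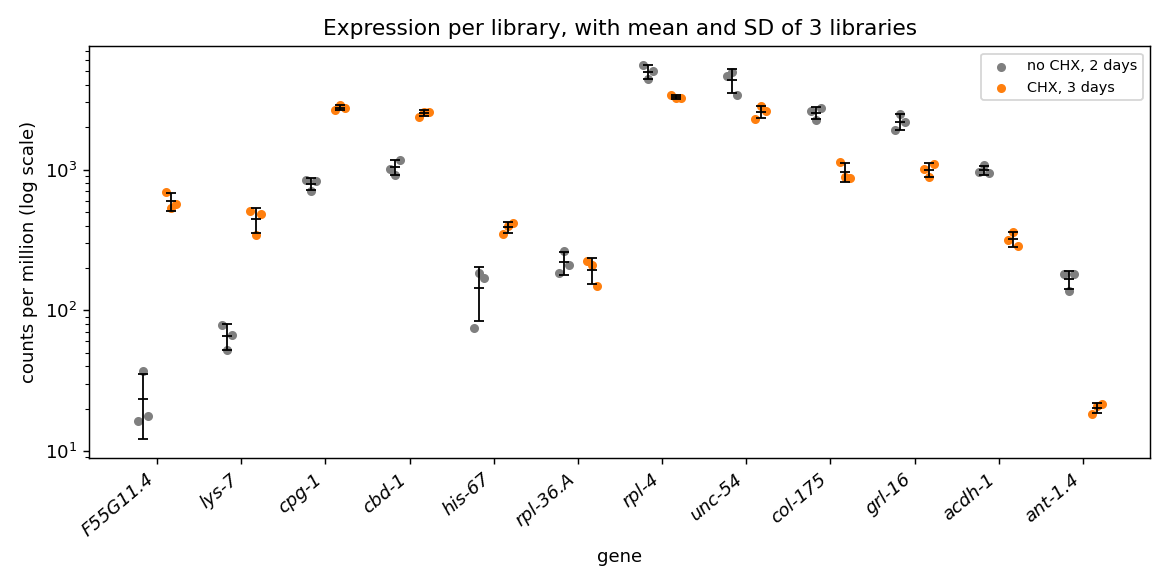
CPM on a log axis for 12 named genes, with the 3 samples per group as points and black marks and bars for mean and SD. The 3 CHX samples of F55G11.4, lys-7, cpg-1, cbd-1 and his-67 lie above all samples without CHX, those of rpl-36.A overlap with them, and those of the other genes lie below.

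Camera with a preset correlation called 17 of 43 tested lists, 5 higher and 12 lower. With an estimated correlation it called 0, with a smallest adjusted p of 0.124 and 11 lists at an unadjusted p under 0.05, while fry called 26 for movement in one direction and 37 for movement in either. Oxidative phosphorylation had an estimated correlation of -0.00463, below the preset 0.01. Its unadjusted camera p still went from 2.27e-06 to 0.00399, so the lost calls do not measure correlation alone. The 9 lists called by fry in one direction and not by camera were F-box genes, higher, and, lower, ribosome biogenesis, translation factors, mitochondrial ribosomal proteins, the integrated stress response, the mitochondrial unfolded protein response, oxidative stress, ABC transporters, and lysozymes and saposins. In the divisions of the samples that mixed the treatments, the preset test still called 15, 10, 12, 5, 1, 3, 10, 11 and 12 lists. Each side of those divisions held more samples of one treatment, so part of the treatment difference remained. These numbers therefore cannot show how often unchanged lists are called, and how far the 17 calls can be trusted stays open. Over 45 gene classes defined by symbol, 9 were called, the classes col, rps, vha, rpl, msp, acdh and alh lower and the classes taf and lin higher. None was called with an estimated correlation (smallest adjusted p 0.308, 7 at an unadjusted p under 0.05). The proton pump gene vha-15 fell 2.09-fold, the aldehyde dehydrogenase gene alh-8 fell 2.00-fold and the general transcription factor gene taf-10 rose from 25.3 ± 3.51 to 71.8 ± 3.39 CPM. The major sperm protein gene msp-50 fell 3.11-fold, with an adjusted p of 0.0501 with DESeq2. Ribosomal protein genes took 9.51% ± 0.276 of counts without CHX and 8.39% ± 0.181 with it, and the mitochondrial genome 0.451% ± 0.0823 and 0.377% ± 0.0249 (SD, n = 3; exact permutation p 0.1 and 0.3).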

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

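List results with library totals and upper-quartile factors were chosen after seeing the data. The 1419 calls were between 1348 and 1474 with RLE or upper-quartile factors, library totals, limma-voom, either other filter, or without sperm, collagen and yolk genes, and 0 of them turned direction under any alternative run. The genes called were not all the same. Under these settings the number shared with the 1419 ran from 1184 with library totals to 1412 with RLE factors, and was 1189 without a low-count filter. DESeq2 called 907 genes, 348 higher and 559 lower, 873 of them shared with the 1419; the cause was not tested. Leaving out each replicate in turn gave 984 to 1331 calls with fewer samples, and 383 to 544 genes higher, the lowest without CHX replicate 3. Replicate numbers did not pair the samples (correlations of deviations -0.05, -0.05 and -0.00, no sample closest to its own number), and a replicate block gave 1225 calls. Of the gene lists, 17 were called with the preset correlation, 0 with an estimated one and 26 with fry; gene classes went from 9 to 0 with an estimated correlation. Named genes gave 2460 alternative values for 165 results: 135 lost a call, 26 gained one and 0 turned direction past the threshold. The depth limits calls of small changes.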

Other observations

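Tests of a scaling error, of a larger germline share as the whole cause and of somatic lists moving alike were chosen only after the result was seen. For the somatic lists, the matched ribosomal lists and the age of CHX replicate 2, the rule for reading the value was also revised after the value was seen, each time to leave the explanation open. Outside the gene lists, 433 tested X-linked genes had a median log2 fold change of -0.44, against 0.10 to 0.15 on the 5 autosomes, and the median difference from 4305 autosomal genes was -0.57 (two-sided permutation of genes, p 1e-05, the smallest possible; genes are not independent replicates). Of all 516 tested X-linked genes, 29 were higher and 140 lower. As a hypothesis, a larger germline share of the RNA may contribute, since the germline expresses X-linked genes at low levels; the value of -0.57 is in line with that, but drug, age and stage may act on the X by other routes that were not tested.

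Genes called higher also lay side by side more often than random placements put them. Of neighbouring tested genes, 84 pairs were both higher, against a mean of 60.5 in 10000 random placements within chromosomes (95% of placements 47 to 75, one-sided p 8e-04). Pairs both lower numbered 153, against a mean of 135 (one-sided p 0.033). That number lay within 95% of placements (117 to 154), so no excess is claimed for lower genes. The longest run of higher genes was on chromosome V from 939391 to 1018350, with Y50D4C.3, sqv-6, unc-34, Y50D4C.5 and ergo-1 at log2 fold changes between 0.99 and 1.37. Another held perm-1, ptc-1 and rev-1 on chromosome II, and one on chromosome X held Y62H9A.3, Y62H9A.5 and ule-5. Shared promoters, operons or tissue clusters may contribute to the 84 pairs, as may reads shared between overlapping neighbours, since the use of strand is not given; these were not told apart by a test.

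The contrast of higher oocyte and lower collagen genes is the main pattern. A scaling error would move both lists alike, but their medians differed by 2.43. This difference restates the pattern and is not a separate test. Coding length is no account of it, since removing the length trend kept 0.98 of the difference. The oocyte median lay 0.95 above the germline median (permutation of genes between the lists, p 1e-05, the smallest possible). Genes are not independent replicates. The gap argues against a larger germline that raised both lists equally as the whole cause. The 2 lists need not rise equally with the germline, however, so the test cannot exclude that cause. A lower share of somatic tissue stays open: body wall muscle (-0.66), intestine (-0.74), neurons (-0.26) and pharynx (-0.22) had medians whose spread gave a permutation p of 0.0777, and the neuron and pharynx lists hold 6 and 8 genes. The neuron median was -0.02 without no_CHX replicate 2 and -0.11 without CHX replicate 3, and the pharynx median -0.33, -0.44 and -0.38 without no_CHX replicate 2, no_CHX replicate 3 and CHX replicate 3. With library totals these medians were -0.10 and -0.06, against -0.51 for muscle and -0.58 for intestine, and with a filter at 5 CPM they were -0.40 and -0.08. Also open, and untested, is that the CHX animals, 1 day older, were further into L4, or that the drug acts on these genes, which the design cannot separate.

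For the lower ribosomal protein genes, the composition factors are not the whole source by the rule set for this test, but only by a narrow margin. With library totals the median moved from -0.27 to -0.114. This was only just past the bound of the rule, a multiple of its spread over libraries (0.0568). The median of all tested genes moved as well, from 0.02 to 0.18. The distance of the ribosomal median from 0 therefore depends on the scaling, while its distance from other genes hardly changed. Camera with the preset correlation still called the list (adjusted p 0.00427). With an estimated correlation its adjusted p was 0.415 with library totals and 0.169 with TMM factors, so the call rests on the preset correlation under either scaling. The fall was not larger than in other genes of like abundance and coding length. The ribosomal median lay at percentile 98.1 of 10000 matched lists, whose medians centred on -0.38 (95% between -0.50 and -0.29). Whether these properties caused the fall stays open. This is outside the range predicted if these properties were the cause, but on the side opposite to the one that would speak against them. Ribosomal protein genes therefore fell less than these matched genes, which may be followed up as a hypothesis with deeper libraries. The pool for matching held all other tested genes with a known coding length, among them collagen, muscle and oxidative phosphorylation genes that fell. How much those genes set the centre of -0.38 was not tested.

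Yolk transcripts in CHX replicate 2 lay a median of 1.76 (log2) above the other CHX samples, with vit-6 at 8504 CPM against 3883 and 4161, near the samples without CHX. Older animals in that library are a candidate explanation, and their oocyte genes would then be higher too. The oocyte median was 0.0962 higher in that library (bootstrap 95% interval 0.0706 to 0.173), below the 0.2 that was predicted but with an interval that crosses the bound of 0.1 set against the explanation. Older animals therefore cannot be told apart from a difference in yolk expression alone.

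The 6 samples make 10 divisions into 3 and 3, too few for a share under 0.05. The real division gave 1419 called genes and 907 changed at least 2-fold, against a highest value of 0 in the other divisions for both. The other divisions put both treatments in each group, which widens the spread within groups. The 0 therefore does not measure how many genes would be called without a treatment effect. For lists the values were 17 and 15, and for classes 9 and 2. The real division was in each case the 1 with the most. For lists the other divisions gave between 1 and 15 calls, so the preset test also called lists when the treatments were mixed. Each side still held more samples of one treatment, so these calls do not measure how often unchanged lists are called.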
